A study of Mus musculus with 37 samples.

How the data were processed

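RNA was measured in mouse cerebellum (strain C57BL/6) from animals with a brain-specific deletion of Mll4, here called KO, and from floxed animals without the deletion, here called WT. Mll4 encodes a methyltransferase of lysine 4 of histone H3. Its current symbol was taken to be Kmt2d. The deposited table uses older symbols and has no Mll4 or Kmt2d. It has Mll2, which the annotation tables give as an older name of both Kmt2d and Kmt2b, and Wbp7, which they give for Kmt2b alone. Mll2 was therefore read as Kmt2d and Wbp7 as Kmt2b, and no coordinates were given that would settle this. Mll1 was read as Kmt2a and Mll3 as Kmt2c. There were 3 WT and 3 KO libraries at 1 month of age and 1 library of each genotype at 4 months. The labels give total RNA prepared with Trizol and sequencing on an Illumina HiSeq instrument. They do not say whether libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. The series has 37 samples. The 29 samples of chromatin immunoprecipitation and its inputs, which include neurospheres, were not analysed here.

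Per the submitters' processing notes, the tools were TopHat2 2.1.0, Bowtie 1.1.2 and Cuffdiff with genome build mm9. The authors deposited 1 table of FPKM values, fragments scaled to transcript length and to the mapped fragments of the library, with 1 column per library. The annotation, the strand setting, the low-value filters and any further scaling between libraries are not given in the sources used here. Because strand is not given, a gene and an overlapping or antisense partner cannot be told apart, and related genes could share reads. The table held 29955 gene symbols and 1 row that repeated older column names, which was removed. Every column was mapped to a sample by its title, and 0 columns were left unmapped. Of the symbols, 19772 matched a current symbol and 2660 an older one (74.9% together) in tables of the GRCm38.p6 annotation. That build differs from mm9, so those tables served for names only and no coordinates are given.

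FPKM values are not read counts, so the absolute depth of the libraries is unknown and no counting intervals are given for expression. In genes under 0.3 FPKM the values of a library are multiples of what 1 fragment is worth. The commonest ratio of such values gave depths relative to WT replicate 1 of 0.971 and 0.731 for WT replicates 2 and 3. For KO replicates 1, 2 and 3 the relative depths were 1.16, 1.2 and 0.771. They were 0.859 for the 4-month WT library and 0.983 for the 4-month KO library. Between 20.2% and 26.1% of the low ratios lay at that commonest value, so these depths are estimates. The total of all FPKM values ran from 381845 in the 4-month KO library to 630615 in the 4-month WT library. Symbols of small nucleolar RNAs, microRNAs and similar short transcripts held 11.0% and 48.1% of those totals.

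Tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. A fold change on this scale understates the change of genes with low values. A gene was tested where its mean over the libraries of the fit was at least 1 FPKM. KO was compared with WT at 1 month in the 6 libraries of that age, with genotype as the only term, in 14847 genes. Age was tested in all 8 libraries with genotype as an additive term, in 14918 genes. That fit takes the effect of genotype to be equal at both ages. P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. At 4 months there was 1 library per genotype. Differences of log2(FPKM + 1) in 14791 genes are therefore given without a p-value, and the median of a gene list is given as its percentile among 10000 random lists of the same size matched on mean expression. Targeted-gene FPKM was also compared with a two-sided exact permutation test, for which 3 against 3 libraries allow no p under 0.1.

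There were 30 gene lists, which held 522 symbols found in the table. They were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list change, not whether they change more than other genes. The lists cover histone and DNA methylation, tumour suppressors and oncogenes, signalling pathways, the cell types of the cerebellum, other tissues a dissection could hold, and metabolism, stress and synapses. Genes were named by a rule. It took the targeted gene, and in each tested comparison the 10 largest fold changes in each direction among genes past the threshold, with at least 2 FPKM in the higher group and no overlap between groups. At 4 months it took the 10 largest differences in each direction among genes of at least 5 FPKM. It also took up to 4 members of each list with the smallest p, and the genes that are the study's subject. Because few genes passed at 1 month, the same rule was also applied at an adjusted p under 10%, and small RNA symbols were left out at 4 months. Both steps, and the counts of list members with age, were chosen after seeing the data. Some genes that the rule names are not reported here.

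The groups, tests, gene lists, rule for named genes and these alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, and quantile normalization or a shift of the libraries to 1 median. Further ones were a trended and robust limma fit, array weights, the replicate number as a block, all 8 libraries with age as a term, a minimum fold of 1.5, an adjusted p under 10%, no genotype term for age, and each library left out in turn. After seeing the data, 4 more were added at 1 month. They left out both libraries numbered 3, averaged replicates 1 and 2 of each genotype, left out small RNA symbols, or added the mean level of brainstem genes as a covariate. Small RNA symbols were also left out at 4 months. On simulated data with 200 changed genes among 14847, the 1-month test recovered 64% of 2-fold and 92% of 4-fold changes with 6 false calls. The test of age, among 14918 genes, recovered 48% of 2-fold and 81% of 4-fold changes with 4 false calls. A planted list was found and 0 other lists were called. The simulated noise was independent between genes, its size was shuffled between genes, and the low means of changed genes were raised. These figures therefore cover neither lists of correlated genes nor large changes that come with a wide spread between libraries. Neurod1, for example, had a log2 fold change of -2.33 at 1 month, at 43.1 ± 43.6 FPKM in KO (SD, n = 3), and did not pass. In the data the estimated correlation was 0.96 for granule neuron genes.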

Results

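The series asks what loss of MLL4 in the brain does to gene expression and chromatin in the mouse cerebellum, with tumour-suppressive genes as its subject. The part analysed here is an FPKM table of 8 libraries of cerebellar RNA. There were 3 WT and 3 KO libraries at 1 month of age and 1 library of each genotype at 4 months. Between 19570 and 20433 genes had a value above 0 in a library. Depth is unknown in absolute terms, and relative to WT replicate 1 it ran from 0.731 in WT replicate 3 to 1.2 in KO replicate 2. Replicates 1 and 2 of each genotype lay closer together than any other pair. Over 7294 genes with a mean of at least 10 FPKM, the median absolute log2 difference was 0.08 between KO replicates 1 and 2 and 0.08 between WT replicates 1 and 2. The library labelled KO replicate 3 differed from KO replicates 1 and 2 by 0.25, and from WT replicates 1 and 2 by 0.16 and 0.15. WT replicate 3 differed from the other WT libraries by 0.19 and 0.18.

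The targeted gene, taken to be Mll2 in the table, had FPKM values of 18.2, 19.9 and 22.3 in the WT libraries at 1 month. It was at 12.7 and 13.6 in KO replicates 1 and 2, and at 23.5 in the library labelled KO replicate 3, above all 3 WT libraries. The means were 16.6 ± 6.04 in KO and 20.1 ± 2.06 in WT (SD, n = 3 each; exact permutation p = 0.4, two-sided). The log2 fold change was -0.31 (SE 0.23), with an adjusted p of 0.393 from limma with Benjamini-Hochberg adjustment. Without the library labelled KO replicate 3 it was -0.58 and passed the threshold in limma. At 4 months the gene was at 46.6 FPKM in the WT library and 16.6 in the library labelled KO. A deletion of some exons need not lower the FPKM of a whole gene, so these values check the labels only in part. Its relatives Mll1, Mll3 and Wbp7, which encode methyltransferases of the same family, had log2 fold changes of -0.37, -0.48 and -0.56, with adjusted p-values of 0.251, 0.144 and 0.122 (limma). For each of them the library labelled KO replicate 3 lay closer to the WT mean than KO replicates 1 and 2 did.

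**Figure D1:**
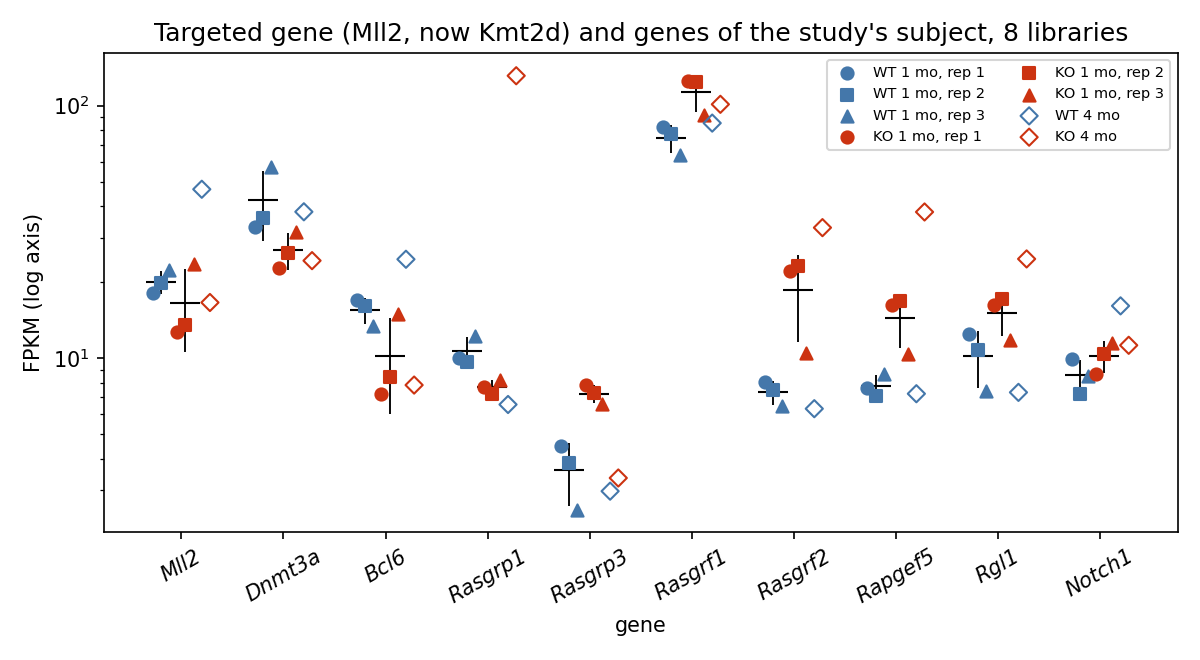
FPKM (log axis) of the targeted gene Mll2 and of 9 genes of the study's subject in each of the 8 libraries, with black bars for the mean and SD of the 3 WT and the 3 KO libraries at 1 month. Mll2 is at 23.5 FPKM in the library labelled KO replicate 3, above the 3 WT libraries, and Rasgrp1 is at 131 FPKM in the library labelled 4-month KO.

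The first comparison asked which genes differ between KO and WT at 1 month. Lgals1, which encodes the sugar-binding protein galectin-1, rose from 7.77 ± 0.278 FPKM in WT to 30.9 ± 5.44 in KO (SD, n = 3 each). The other 3 genes that changed carry only accession-like symbols. AK185715 was listed at 0 in every WT library and at 2.04, 3.11 and 3.28 FPKM in the KO libraries. AK219843 was listed at 0 in every KO library and at 25.4, 25.7 and 45.0 FPKM in the WT libraries. AK140370 fell from 12.8 ± 1.24 to 3.27 ± 0.371 FPKM. Of 14847 genes tested, these 4 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, with adjusted p-values of 0.0245, 0.0245, 0.00236 and 0.0245 in the order named. An unadjusted p under 0.05 was reached by 4636 genes, 2083 higher and 2553 lower, where chance gives 742. In 5308 genes (35.8%) the 2 groups did not overlap, where chance gives 10% of genes with 3 libraries against 3.

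The count of genes depended on the libraries included. Without the library labelled KO replicate 3 limma called 5037 genes, 2103 higher and 2934 lower, and array weights, which give each library its own weight, called 8095. Leaving out WT replicate 1, WT replicate 3 or KO replicate 1 gave 1, 18 and 2 genes, and the replicate number as a block gave 0 in limma, with 4892 at an unadjusted p under 0.05. Quantile normalization called 8 genes, 6 of them higher, and a shift of the libraries to 1 median called 42, 36 of them higher.

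At an adjusted p under 10%, a threshold applied after the count at 5% was seen, 2381 genes passed, 1183 higher and 1198 lower. With the libraries shifted to 1 median 2331 passed, 1457 higher and 874 lower. Leaving out WT replicates 1, 2 and 3 in turn gave 1, 5 and 486 genes at that threshold, leaving out KO replicates 1 and 2 gave 7 and 5, leaving out the library labelled KO replicate 3 gave 6645, and the brainstem covariate gave 1. The largest negative changes included Neurod1, a transcription factor of granule neurons, at 163 ± 17.8 FPKM in WT and 43.1 ± 43.6 in KO (SD, n = 3 each; log2 fold change -2.33, adjusted p = 0.081, limma). Cnpy1 was at 106 ± 12.1 and 26.3 ± 29.7 FPKM, and Car8, a carbonic anhydrase-related protein of Purkinje cells, at 213 ± 20.6 and 54.6 ± 45.7. Fat2, Ltbp2 and Il16 had log2 fold changes of -2.26, -2.30 and -2.20. Among the largest positive changes, Lyz2, the lysozyme of myeloid cells, was at 4.56 ± 2.21 FPKM in WT and 35.6 ± 9.08 in KO (log2 fold change 2.78, adjusted p = 0.0612, limma). Cd74 and H2-Aa, which serve antigen presentation on MHC class II, had log2 fold changes of 2.77 and 2.29, and complement C3 of 3.36. Prph, Slc5a7 and Slc18a3, genes of motor and cholinergic neurons, and the homeobox gene Hoxa5 had log2 fold changes of 2.59, 2.50, 2.40 and 2.30.

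Genes of both main neuron types of the cerebellar cortex fell as lists in KO at 1 month. All 17 granule neuron genes tested had a negative fold change, with a median of -1.63, and so did all 16 Purkinje cell genes, with a median of -1.73. Gabra6, a GABA receptor subunit of granule neurons, was at 219, 213 and 217 FPKM in the WT libraries, at 29.5 and 28.5 in KO replicates 1 and 2, and at 145 in the library labelled KO replicate 3. Pcp2, a marker of Purkinje cells, was at 517, 429 and 365 FPKM in WT and at 66.7, 52.7 and 273 in KO. When adjusted over the list alone, 17 of the granule neuron genes and 15 of the Purkinje cell genes passed, among them Calb2 (log2 fold change -1.08), Zic1 (-1.89), Stk17b (-1.69) and Pcp4 (-1.21), while 0 passed among all genes tested at 5%. The camera adjusted p-values were 3.05e-07 and 2.6e-07, and the adjusted p was 0.501 for both lists with an estimated correlation. The lists' medians relative to the WT mean were -2.34 and -2.24 in KO replicate 1, and -0.45 and -0.66 in the library labelled KO replicate 3. With the mean level of brainstem genes as a covariate, chosen after seeing the data, the medians were -0.49 and -0.29 and neither list was called, the only 1 of 20 alternative settings that ended these calls.

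Brainstem genes rose as a list, with a median log2 fold change of 1.65 over 14 genes, all positive. Chat, the enzyme that makes acetylcholine, was at 0.947 ± 1.25 FPKM in WT and 7.18 ± 1.38 in KO (SD, n = 3 each), Calca at 1.67 ± 1.31 and 9.25 ± 0.322, and Hoxb2 at 0.722 ± 0.724 and 3.99 ± 0.388. Of the 14, 13 passed when adjusted over the list alone, all higher. The camera adjusted p was 8.04e-10, and the adjusted p was 0.464 with an estimated correlation. The same genes were higher in WT replicate 3, with a list median of 0.72 relative to the WT mean, than in WT replicates 1 and 2, at -0.35 and -0.37. Only the covariate built from these genes themselves ended the call among 20 alternative settings.

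Oligodendrocyte genes rose by a median of 0.56 over 15 genes and oligodendrocyte precursor genes by 0.43 over 12, all with positive fold changes. Aspa, an enzyme of myelin lipid synthesis, was at 18.0 ± 1.51 FPKM in WT and 37.3 ± 8.22 in KO (SD, n = 3 each), and Bcas1 at 58.8 ± 8.98 and 139 ± 44.6. The genes that passed when adjusted over the list alone were 4 and 2, all higher. The camera adjusted p-values were 0.000483 and 0.00516, and the adjusted p was 0.568 for both with an estimated correlation. The oligodendrocyte list stood at 0.58 in WT replicate 3 and at -0.09 in the library labelled KO replicate 3, relative to the WT mean. Its median was 0.86 without WT replicate 3 and 0.85 without the library labelled KO replicate 3. The median of the precursor list was 0.25, 0.27 and 0.75 without WT replicate 1, 2 or 3. With the brainstem covariate both lists were called with negative medians, -1.14 and -0.76, and with all 8 libraries and age as a term neither was called.

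Microglia genes rose as a list in KO at 1 month, with all 15 genes positive and a median log2 fold change of 0.92. C1qc, a chain of the complement component C1q, was at 11.3 ± 1.74 FPKM in WT and 31.0 ± 5.85 in KO (SD, n = 3 each). Csf1r, the receptor for the microglial growth factor CSF1, was at 11.4 ± 0.532 and 22.3 ± 1.08 FPKM, C1qb at 10.1 ± 2.75 and 28.6 ± 4.84, and Cx3cr1 at 4.47 ± 0.697 and 8.81 ± 0.495. All 15 passed when adjusted over the list alone. The camera adjusted p was 8.09e-11, and the adjusted p was 0.464 with an estimated correlation. The list was above the WT mean by 0.88, 0.78 and 1.42 in KO replicates 1 and 2 and the library labelled KO replicate 3, and it was called under all 20 alternative settings.

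Genes of interferon response and antigen presentation rose as a list by a median of 0.60 over 16 genes, and genes of meninges and fibroblasts by 0.54 over 11. H2-K1, an MHC class I gene, was at 8.29 ± 3.6 FPKM in WT and 21.2 ± 3.67 in KO (SD, n = 3 each), Ifit2 at 1.72 ± 0.394 and 3.29 ± 0.519, and Gbp3 at 1.41 ± 0.0565 and 2.44 ± 0.218. Col3a1, a fibrillar collagen, was at 5.76 ± 0.715 and 17.6 ± 2.49 FPKM, and Dcn at 10.1 ± 2.84 and 24.3 ± 7.19. Adjusted over the list alone, 10 genes of the interferon list were higher and 1 was lower, and 7 genes of the meninges list were higher. The camera adjusted p-values were 0.000397 and 0.000483, and the adjusted p was 0.464 for both with an estimated correlation. With all 8 libraries and age as a term neither was called, and with a filter at 5 FPKM the interferon list had a median of 0.00 and was not called.

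**Figure D2:**
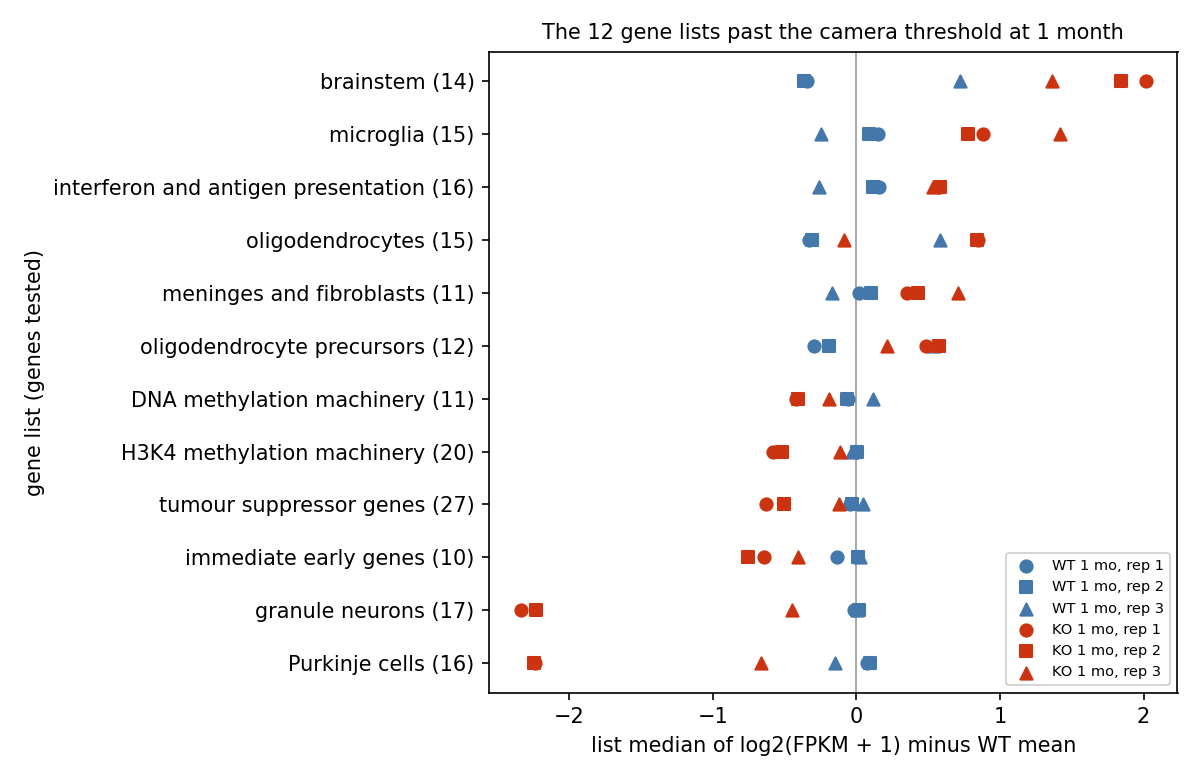
Median over each of the 12 gene lists past the camera threshold of log2(FPKM + 1) minus the mean of the 3 WT libraries, with 1 point per 1-month library and the number of genes tested in parentheses. KO replicates 1 and 2 lie together in every list, at -2.34 and -2.23 for granule neurons, where the library labelled KO replicate 3 is at -0.45.

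Genes of the machinery that writes or removes methylation of histone H3 lysine 4 fell as a list by a median of 0.35 on the log2 scale, and DNA methylation genes fell by 0.31. Kdm6a, a histone demethylase that works in the same complex as MLL4, was at 22.6 ± 4.93 FPKM in WT and 13.6 ± 2.48 in KO (SD, n = 3 each), and Kdm5b at 23.3 ± 2.59 and 16.3 ± 2.05. Mbd4, a DNA repair glycosylase, was at 5.8 ± 0.363 and 3.16 ± 0.944 FPKM, and Tet3, which oxidises methylated cytosine, at 20.2 ± 4.07 and 10.7 ± 4.33. Negative fold changes were found in 18 of 20 and 9 of 11 genes, and 0 and 1 passed when adjusted over the list alone. The camera adjusted p-values were 0.00262 and 0.0351, and the adjusted p was 0.501 for both with an estimated correlation. The H3K4 list stood at -0.58 and -0.52 in KO replicates 1 and 2 and at -0.11 in the library labelled KO replicate 3, relative to the WT mean, and without that library its median was -0.57. With the brainstem covariate neither list was called. The DNA methylation list also lost its call under quantile normalization, a filter at 5 FPKM and all 8 libraries with age.

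Tumour suppressor genes fell as a list by a median of 0.39 on the log2 scale, with negative fold changes in 22 of 27 genes. Cdkn1b, an inhibitor of cyclin-dependent kinases, was at 52.3 ± 2.85 FPKM in WT and 27.9 ± 7.16 in KO (SD, n = 3 each), Sirt1 at 10.9 ± 0.281 and 6.22 ± 2.06, and Foxo3 at 45.9 ± 0.216 and 25.3 ± 9.98. Dnmt3a, a DNA methyltransferase, was at 42.1 ± 13.1 and 26.8 ± 4.4 FPKM (log2 fold change -0.61, adjusted p = 0.135, limma). Bcl6, a transcriptional repressor, was at 15.5 ± 1.87 and 10.2 ± 4.17 FPKM (log2 fold change -0.61, adjusted p = 0.158, limma), with 15 in the library labelled KO replicate 3. Cdkn1b alone passed when adjusted over the list alone, and Dnmt3a and Bcl6 did not pass among all genes. The camera adjusted p was 0.00497, and the adjusted p was 0.553 with an estimated correlation. Dnmt3a and Bcl6 are the study's subject, so their place in the list is not independent evidence of its direction. The list stood at -0.63 and -0.50 in KO replicates 1 and 2 and at -0.12 in the library labelled KO replicate 3, relative to the WT mean. Its median was -0.60 without that library, -0.20 without WT replicate 3 and -0.24 without KO replicate 1. With the brainstem covariate the list was not called.

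Immediate early genes, which neurons induce with activity, fell as a list by a median of 0.65 on the log2 scale. Egr1 was at 7.38 ± 0.84 FPKM in WT and 4.14 ± 0.0963 in KO (SD, n = 3 each), Nr4a2 at 5.74 ± 2.12 and 2.18 ± 0.254, and Nr4a1 at 8.24 ± 4.38 and 2.67 ± 0.095. Of 10 genes 5 passed when adjusted over the list alone, all lower. The camera adjusted p was 0.0129, and the adjusted p was 0.464 with an estimated correlation. With a filter at 5 FPKM, or with all 8 libraries and age as a term, the list was not called.

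Activators and effectors of Ras were not called by camera as a list at 1 month (median 0.06, adjusted p = 0.224), with 15 genes positive and 14 negative. Fry's mixed test, for change in either direction, called them (adjusted p = 0.0118), as it called 16 of the 30 lists. That test does not compare a list with other genes, and 4636 of all 14847 genes had an unadjusted p under 0.05 in limma. Its calls therefore do not show a change particular to a pathway. Adjusted over the list alone 4 genes passed, all higher, namely Rasgrp3 (log2 fold change 0.86), Rapgef3 (0.52), Rapgef5 (0.79) and Rasgrf2 (1.16). The exchange factor Rasgrp1 was at 10.7 ± 1.43 FPKM in WT and 7.71 ± 0.507 in KO (SD, n = 3 each; adjusted p = 0.0957, limma). Rapgef5 was at 7.8 ± 0.809 and 14.5 ± 3.52 FPKM (adjusted p = 0.0761, limma), Rasgrf1 at 74.4 ± 9.33 and 113 ± 19.0 (adjusted p = 0.0875, limma) and Rgl1 at 10.2 ± 2.6 and 15.1 ± 2.87 (adjusted p = 0.156, limma). Of the Notch pathway, Notch1 was at 8.55 ± 1.33 and 10.2 ± 1.45 FPKM (adjusted p = 0.33, limma). Adjusted over the list alone 4 Notch genes were higher, Mfng (0.65) and Heyl (0.53) among them, and 4 were lower, with Dner at -0.83 and Numbl at -0.74. The adjusted p of the Notch list was 0.93 in camera and 0.0098 in fry's mixed test.

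Camera called none of the other lists of growth control, fry called MAPK feedback targets (adjusted p = 0.0186), and fry's mixed test called these and Sonic hedgehog genes (adjusted p = 0.0177 and 0.0166). Sonic hedgehog genes had a median of 0.13 and a mean of -0.05 (camera direction up, adjusted p = 0.524), with Boc at -1.39 and Sfrp1 at 0.75, and adjusted over the list alone 4 were higher and 5 lower. Wnt targets had a median of 0.00 (adjusted p = 0.247, with 1 gene higher when adjusted over the list alone), cell proliferation genes -0.07 (adjusted p = 0.93), medulloblastoma oncogenes -0.10 (adjusted p = 0.317) and MAPK feedback targets -0.16 (adjusted p = 0.0615). Camera called the last list without WT replicate 3 (-0.25), KO replicate 1 (-0.20) or KO replicate 2 (-0.22). Among MAPK feedback targets, Dusp5 was at 34.9 ± 3.7 FPKM in WT and 8.07 ± 5.04 in KO (SD, n = 3 each) and passed when adjusted over the list alone. Etv1 (-1.27) of that list is also in the granule neuron list. Dusp5 was at 5.71, 4.65 and 13.9 FPKM in KO replicates 1, 2 and 3, and Boc at 7.95, 8.39 and 22.5. Granule neuron genes were likewise lowest in KO replicates 1 and 2. Whether the pathway lists changed apart from cerebellar neuron genes was not tested. Granule precursors and immature neurons had a median of -0.21 (adjusted p = 0.108), with 2 genes lower when adjusted over the list alone. None of the proliferation genes and oncogenes passed in that way.

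The remaining lists were not called by camera with all 6 libraries. Cerebellar interneuron genes had a median of 0.14 and a mean of -0.04 (camera direction up, adjusted p = 0.495), with 3 genes higher and 2 lower when adjusted over the list alone, among them the glycine transporter Slc6a5 at 1.85 and Eomes, a marker of unipolar brush cells, at -1.70. Genes of Bergmann glia and astrocytes had a median of 0.01 and a mean of -0.19 (camera direction down, adjusted p = 0.93), with 3 higher and 5 lower when adjusted over the list alone, Gfap at 1.19 and the glutamate transporter Slc1a3 at -1.32. Vascular genes had a median of 0.13 (adjusted p = 0.084), choroid plexus genes -0.20 (adjusted p = 0.898), and genes of forebrain and midbrain a median of -0.05 and a mean of 0.05 (camera direction up, adjusted p = 0.532), with 2 higher and 1 lower when adjusted over the list alone. Globin and other blood genes had a median of 1.25 (adjusted p = 0.207), with Hba-a2 at 801 FPKM in the library labelled KO replicate 3 and 373 in WT replicate 3, against 72.1 to 197 in the other 1-month libraries. Synaptic receptors and channels had a median of -0.37 (adjusted p = 0.0535), with 2 higher and 11 lower when adjusted over the list alone, oxidative phosphorylation 0.07 (adjusted p = 0.0598), glycolysis 0.09 (adjusted p = 0.247) and stress response 0.06 (adjusted p = 0.467). Some of these lists were called by camera when 1 library was left out. Synaptic receptors and channels were called without WT replicate 2 (-0.41), WT replicate 3 (-0.38), KO replicate 1 (-0.29), KO replicate 2 (-0.34) or the library labelled KO replicate 3 (-0.42). Oxidative phosphorylation was called without WT replicate 2 (0.10) or the library labelled KO replicate 3 (0.20), choroid plexus without the latter (-0.61) and blood without WT replicate 3 (2.14). Without the library labelled KO replicate 3 the median was 0.45 for blood, 0.28 for forebrain and midbrain and -0.01 for stress response. Of the 30 lists camera called 12, 6 higher and 6 lower. With an estimated correlation it called 0 (smallest adjusted p = 0.464), fry called 4 (microglia, meninges, immediate early genes and MAPK feedback targets) and its mixed test 16. Among the lists of this paragraph the mixed test called cerebellar interneurons (adjusted p = 0.00582), Bergmann glia and astrocytes (0.00582), forebrain and midbrain (0.00654), synaptic receptors and channels (0.0171) and glycolysis (0.0241). The median of all genes was -0.04.

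The pair of 4-month libraries asked the same question at an older age, with no replicate check. In the library labelled KO 16 of 17 granule neuron genes and 15 of 16 Purkinje cell genes were lower than in WT, by very different amounts. Gabra6 was at 0.118 FPKM in it and at 134 in WT, Fat2 at 0.214 and 136, Pcp2 at 0.544 and 132, and En2, a homeobox gene of midbrain and cerebellum, at 0.106 and 28.7. Over Gabra6, Fat2, Cbln3, Pcp2, Car8 and En2, a set chosen after the values were seen, the median was 0.283% of the WT level. Over all 33 granule neuron and Purkinje cell genes the median was 10.2% of the level in WT replicates 1 and 2 at 1 month (interquartile range 1.86 to 26.1). Other members of these lists, also chosen after their values were seen, were lower by less or were higher. Slc17a7 was at 252 FPKM against 126, Pcp4 at 192 against 222, Itpr1 at 125 against 356 and Calb1 at 26.6 against 167. The lists were not limited to genes that the forebrain lacks, so these values do not show that cerebellar neurons were present. Genes of the forebrain stood high in the same library. Tbr1, a transcription factor of cortical neurons, was at 31.2 FPKM against 0.162 in WT, Neurod6 at 33.2 against 1.6, and Camk2a, chosen after its values were seen, at 385 against 16.1. The 1-month KO libraries had Tbr1 at 0.0397, 0.135 and 0.15 FPKM.

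**Figure D3:**
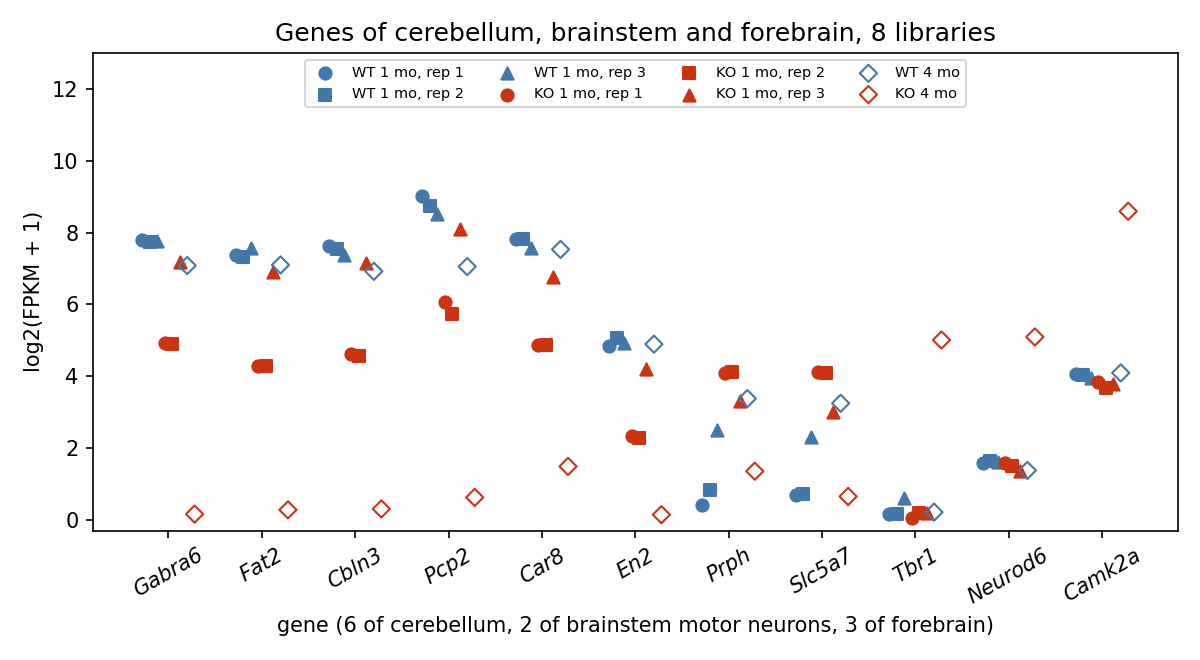
Log2(FPKM + 1) of 6 genes of cerebellum, 2 of brainstem motor neurons and 3 of forebrain in each of the 8 libraries. The library labelled 4-month KO holds Gabra6 at 0.118 FPKM and Tbr1 at 31.2 FPKM, and no other library has Tbr1 above 0.537 FPKM.

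By the rule of size, the largest differences at 4 months that were not small RNAs were Gabra6 (-6.92), Fat2 (-6.82) and Cbln3 (-6.62) among lower genes. Ddn (6.76), Nrgn (6.54), Egr3 (5.22) and Gda (5.07) led the higher ones, beside Crym at 33.2 FPKM against a listed 0, and Ddn and Nrgn encode postsynaptic proteins of forebrain neurons. Small RNA symbols took 8 of the 20 places. Snord116 was first among them, listed at 0 in the 4-month KO library and also at 0 in WT replicate 1 and in KO replicates 1 and 3 at 1 month. Of 14791 genes 3068 differed by at least 2-fold, 1415 higher and 1653 lower, and pairs of WT libraries at 1 month had 163 to 468 such genes. Granule neuron genes had a median difference of -3.23 and Purkinje cell genes of -2.87, both at percentile 0 among random lists. Genes of forebrain and midbrain had a median of 2.87, immediate early genes of 1.49 and microglia genes of 0.96, all 3 at percentile 100. Brainstem genes had a median of -1.92 (percentile 0.01) and oligodendrocyte genes of -0.71 (percentile 0.08). The filter on low values left 7 brainstem, 15 immediate early and 10 forebrain and midbrain genes at 4 months, against 14, 10 and 5 at 1 month.

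Among the genes of the study's subject, Dnmt3a was at 24.3 FPKM in the library labelled 4-month KO and 38.0 in WT, and Bcl6 at 7.84 and 24.7. Rasgrp1 was at 131 and 6.57, Rapgef5 at 37.9 and 7.24, Rgl1 at 24.7 and 7.33, and Notch1 at 11.3 and 16.1. Tumour suppressor genes had a median difference of -0.40 (percentile 0.34), Notch genes of -0.43 (percentile 0.66) and Ras activators and effectors of 0.24 (percentile 90.8). All of these values come from the library with forebrain genes high and most cerebellar neuron genes low.

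Across ages, the sign of the 1-month change was compared with that of the 4-month difference. Of the 12 lists called at 1 month, the medians of H3K4 methylation, DNA methylation, tumour suppressor, microglia, granule neuron and Purkinje cell genes had the same sign at 4 months, for DNA methylation genes at a median of -0.04 (percentile 42.9) with 5 genes higher and 6 lower. Those of brainstem, immediate early, interferon, meninges, oligodendrocyte and oligodendrocyte precursor genes had the opposite sign. Of the 4 genes called at 1 month 3 were also tested at 4 months, and 1 of them, AK140370, had the same sign (33.3%, exact 95% binomial interval 0.84 to 90.6). Of the 2254 genes at an adjusted p under 10% (limma), 1362 had the same sign (60.4%), against 57.8% of all 14261 genes tested at both ages. Those 2254 come from the 2381 genes at 1 month, a count that was 1 to 486 when WT replicate 1, 2 or 3 or KO replicate 1 or 2 was left out. Across all 14261 genes, which are not independent replicates, Pearson's r was 0.265 and Spearman's rho 0.256. The comparisons share no library, and the direction at 4 months rests on the library labelled KO with forebrain genes high. Without the library labelled KO replicate 3 the share was 66.4%, and without WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2 it was 0%, over 1 to 3 genes.

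**Figure D4:**
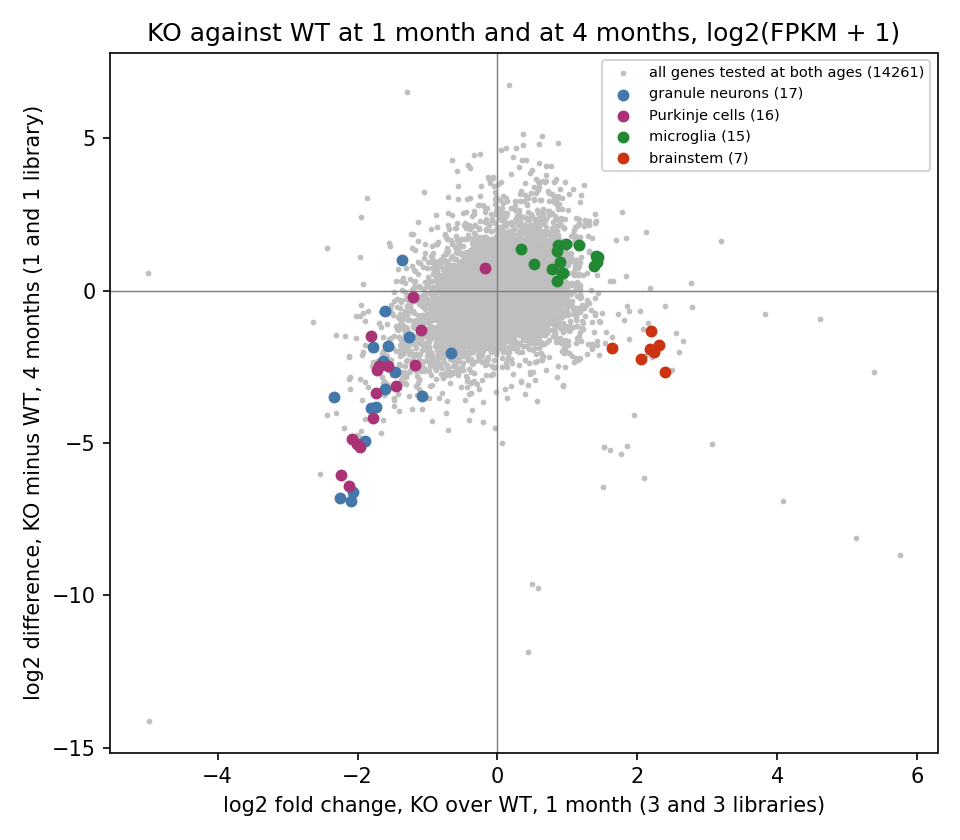
Log2 fold change of KO over WT at 1 month (x axis, 3 and 3 libraries) against the log2 difference of KO minus WT at 4 months (y axis, 1 and 1 library) for the 14261 genes tested at both ages, with 4 gene lists coloured. Granule neuron and Purkinje cell genes are negative at 1 month and, except for Slc17a7 and Foxp2, at 4 months, microglia genes are positive on both, and brainstem genes are positive at 1 month and negative at 4 months.

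Age was compared as 2 libraries at 4 months against 6 at 1 month, where age and any sequencing batch cannot be told apart. The library labelled KO with forebrain genes high is 1 of the 2 at 4 months. Fabp7, a fatty acid binding protein of Bergmann glia and precursors, fell from 49.3 ± 12.2 FPKM (SD, n = 6) at 1 month to 14.3 and 11 in the 4-month WT and KO libraries. Enpp6, a gene of newly formed oligodendrocytes, fell from 13.5 ± 5.01 to 2.43 and 2.79 FPKM, the metallothionein Mt1 from 501 ± 87.8 to 105 and 196, and Calb2 from 176 ± 71.1 to 82.5 and 6.62. Among the genes that rose were Shank1, a scaffold of the postsynaptic density, from 32.6 ± 10.5 to 113 and 84.9 FPKM, and Psd from 25.6 ± 2.93 to 58.8 and 117. The growth regulator Nov went from 2.71 ± 1.1 to 8.99 and 57.4 FPKM. Without the 4-month KO library the log2 fold change with age went from -2.70 to -1.52 for Calb2, from 1.67 to 1.1 for Psd and from 2.75 to 1.77 for Nov, and Enpp6 and Shank1 no longer passed (adjusted p = 0.0625 and 0.0565, limma). Snora33 was listed at 0 in both 4-month libraries, and AK185771 was at 3.75 and 4.46 FPKM there and at 0.0128 ± 0.0314 at 1 month.

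Of 14918 genes limma called 295 with age, 112 higher and 183 lower, with Benjamini-Hochberg adjusted p-values from 0.000806. The median of all genes was -0.10, and quantile normalization called 222 genes with the opposite balance, 143 higher and 79 lower. A shift of the libraries to 1 median called 214, 157 higher and 57 lower. Genes of oxidative phosphorylation were lower, with a median log2 fold change of -0.65 over 30 genes, -0.47 under quantile normalization and -0.69 in the WT libraries alone. In that list 9 genes passed at 5% among all genes, Atp5e (-0.96) and Cox6c (-0.80) among them, named after their values were seen, and 25 when adjusted over the list alone. Oligodendrocyte genes had a median of -1.53, or -0.97 in the WT libraries alone, with Mobp (-1.73) past the threshold and 14 of 15 genes past it when adjusted over the list alone. Limma called 1531 genes without the 4-month KO library, 2278 without the 4-month WT library, 550 without the library labelled KO replicate 3, 5 without WT replicate 3, and 2 without each of the other 4 libraries at 1 month.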

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

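The tests of mixing, of granule neuron loss, of microglia genes in single libraries, of blood, of both explanations for the 4-month KO library and of the gene count over splits were chosen after the results were seen. The brainstem covariate was added after the data were seen and before its own result was known.

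Granule neuron and Purkinje cell genes were lower together in the 1-month libraries labelled KO. Loss of granule neurons alone would leave Purkinje cell genes level or higher, and their median was -1.73, and scaling of the libraries was argued against by a granule neuron median of -1.56 under quantile normalization. If brainstem tissue were the whole cause, the brainstem level of the library labelled KO replicate 3 predicts 50.7% of the WT cerebellar level, where 66.3% was seen (interquartile range 57.7 to 73.6 over 33 genes). In WT replicate 3 it predicts 77.5%, where 87.3% was seen (81.1 to 108), and although both libraries lie above the prediction, its ranges, computed afterwards from the brainstem genes, were 44.6 to 68.3 and 72.6 to 85.4 and overlap what was seen, so brainstem tissue stays open. With the brainstem covariate the granule neuron median went from -1.63 (interquartile range -1.89 to -1.47) to -0.49 (-0.56 to 0.05), and since that covariate correlates with genotype at 0.904 and raised the median standard error from 0.50 to 1.03, dissection and an effect of genotype cannot be told apart for these genes by it.

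Microglia genes were higher in the 1-month libraries labelled KO. With the brainstem covariate the microglia median was 1.48 (interquartile range 1.21 to 2.23), but that covariate correlates with genotype at 0.904. By itself it cannot tell dissection and genotype apart. In the library labelled KO replicate 3, 12 of 15 genes were higher than in KO replicates 1 and 2, by a median of 0.38. Its brainstem genes are lower than theirs. WT replicate 3 has higher brainstem genes than WT replicates 1 and 2, and 4 of 15 microglia genes above their mean (median difference -0.37). Both go against brainstem tissue, but each comparison rests on 1 library. Blood left in the tissue would raise microglia genes in WT replicate 3, which has more globin RNA than KO replicates 1 and 2, yet 15 of 15 were lower there. That rests on 1 library, and the library labelled KO replicate 3 had both the highest Hba-a2 (801 FPKM) and the highest microglia median (1.42) at 1 month, so blood stays open. A change in the number or state of microglia in KO was not tested. The Mll2 level, which checks the labels only in part, goes against the label of KO replicate 3, 1 of the 3 libraries behind this direction. The untargeted Mll1, Mll3 and Wbp7 also lay closer to the WT mean there than in KO replicates 1 and 2. AK219843 was listed at 0 there, as in the other KO libraries, and at 25.4 to 45.0 FPKM in WT. That gene was called from these same libraries, so the label stays unsettled.

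The library labelled 4-month KO had forebrain genes high and most cerebellar neuron genes low. Outgrowth of granule precursor-like cells would raise proliferation genes, whose median difference of -0.28 over 4 higher and 6 lower genes (-1.08 to 1.22) decides nothing, so it stays open. Forebrain tissue in this library, whether from dissection or from a sample mix-up, also stays open. The median of 6 cerebellar genes was 0.283% of the WT level, but they were chosen because they were low, and over all 33 granule neuron and Purkinje cell genes it was 10.2% of WT replicates 1 and 2 (interquartile range 1.86 to 26.1). Those lists were not limited to genes that the forebrain lacks, so the median over 33 genes does not count against forebrain tissue. The library alone stands for KO at 4 months, so an effect of genotype at that age was not tested.

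Among the called lists, and among the called genes and 16 genes of the study's subject, 4 lists and 5 genes had all 3 KO libraries at 1 month on one side of WT and the 4-month KO library on the other. The difference between ages was not tested in any of them, and lists that were not called and other named genes, such as Lyz2 (2.78 and -0.54), also had it. The 4-month differences of the lists were -0.23 for meninges and fibroblasts, -1.92 for brainstem, 1.49 for immediate early genes and -0.44 for interferon and antigen presentation, where the 1-month medians were 0.54, 1.65, -0.65 and 0.60. The filter on low values left different members at the ages, 7 brainstem and 15 immediate early genes at 4 months against 14 and 10 at 1 month. Those of the genes were 0.60 for AK219843, -0.49 for Lgals1, 4.13 for Rasgrp1, -0.29 for Jag1 and -0.67 for Dll1.

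The 6 libraries at 1 month can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4 genes, 1 of the 10 splits gave as many, and the highest other split gave 1 gene. For gene lists the real split gave 12, 1 of the 10 splits gave as many, and the highest other split gave 9.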

How the results depend on the processing

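Settings that leave out both libraries numbered 3, average replicates 1 and 2, leave out small RNAs or add the brainstem covariate were chosen after seeing the data. The count of 4 genes at 1 month was 12 with a pseudocount of 0.1, 1 with no filter, 13 with a filter at 5 FPKM, 8 under quantile normalization, 42 with the libraries shifted to 1 median, 9 with limma's trended and robust fit, 8095 with array weights, 6997 without both libraries numbered 3, 19 without small RNAs and 2381 at an adjusted p under 10%. Limma called 0 with all 8 libraries and age, with replicates 1 and 2 averaged and with the brainstem covariate, with 3937, 1433 and 1460 genes at an unadjusted p under 0.05. Leaving out 1 library gave 1 to 5037 genes, the highest without the library labelled KO replicate 3. Camera called 12 gene lists, 7 with all 8 libraries and 0 with an estimated correlation, fry called 4, of which MAPK feedback targets were not among the 12, and microglia genes were called in 20 of 20 settings. With the brainstem covariate the medians of oligodendrocytes (-1.14), oligodendrocyte precursors (-0.76) and choroid plexus (0.74) turned, and the cause was not tested. The targeted gene passed limma's threshold with array weights (-0.50), without both libraries numbered 3 (-0.50) and without KO replicate 3, and leaving out 1 library gave -0.58 to -0.15. The share of genes with the same sign at 4 months was 0% with no filter and 0 to 66.4% when 1 library was left out. The count at 4 months was 1476 with a pseudocount of 5. The 295 genes with age became 163 and 675 with pseudocounts of 0.1 and 5, 447 with no filter, 671 with a filter at 5 FPKM, 2 with array weights, 3 with no genotype term, and 2 to 2278 when 1 library was left out, the highest without the 4-month WT library. Of the results for single genes at 1 month under these settings 2531 kept their side of the threshold, 408 came to pass it and 33 no longer did. For age 187 kept it and 147 no longer passed, and for lists 549, 32 and 16. A change of sign between values that both missed the threshold was counted as kept. Where a group was left with 1 library, it was taken to vary like the others. The cause of the other moves was not tested. Absolute depth is unknown, so what it limits was not measured.

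With the replicate number as a block limma called 0 genes at 1 month, with 4892 at an unadjusted p under 0.05 and 2700 at an adjusted p under 10%. Over all genes the deviations of same-numbered libraries correlated at 0.166, 0.0278 and 0.0399, which shows little pairing by number but does not exclude it. Both libraries numbered 3 had the lowest relative depths (0.731 in WT and 0.771 in KO). They also had the highest Hba-a2 at 1 month, at 373 FPKM in WT and 801 in KO.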

Other observations

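The genes Gfap, Serpina3n, C4b and H2-Ab1, chosen after their values were seen, stood high in the libraries labelled KO at 1 month. They are single genes and stand for no list, and genes of Bergmann glia and astrocytes, a list fixed in advance, had a median log2 fold change of 0.01 (adjusted p = 0.93 in camera and 0.00582 in fry's mixed test), with 3 higher and 5 lower when adjusted over the list alone. Gfap, an intermediate filament of astrocytes, was at 153, 154 and 301 FPKM in KO replicates 1, 2 and 3, and at 80.6, 83.2 and 87.4 in WT. Serpina3n, a protease inhibitor of reactive astrocytes, was at 12.1, 12.1 and 20.0 FPKM in KO and at 2.15, 1.74 and 3.82 in WT. C4b, a complement component, was at 8.84, 9.09 and 12.9 FPKM in KO and at 2.6, 2.41 and 2.16 in WT. H2-Ab1, an MHC class II chain, was at 7.99, 7.61 and 3.31 FPKM in KO and at 0.938, 1.14 and 0.611 in WT. Their adjusted p-values in limma were 0.0703, 0.0612, 0.0543 and 0.0639, so none passed at 5%. At 4 months Gfap was at 67.1 FPKM in the library labelled KO and 77.0 in WT, and C4b at 2.98 and 5.83.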
